A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

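RNA levels were measured in cultures of the budding yeast Saccharomyces cerevisiae that constitutively expressed either wild-type SPT15 (SPT15-WT) or the spt15-A101T allele. SPT15 encodes the TATA-binding protein, which recruits the transcription machinery to promoters. Per the labels' protocols, the cells grew in SD minimal medium supplemented with amino acids, were collected in exponential growth at an OD600 of 1.5, and gave total RNA that was treated with DNase. Cy3-labelled cRNA was made from it by amplification from an oligo-dT primer, per the labels' protocols, so the arrays report polyadenylated transcripts. Each of the 4 samples, 2 per group, was hybridised alone to 1 array of an Agilent 1-colour yeast design (design 016333). The labels number the samples of each group and do not say whether they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

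The deposited scanner output was made with Agilent Feature Extraction 11.5.1.1, per the file headers. It gives the intensity of each spot on a linear scale, as a processed signal with background subtracted and spatial trends removed and as raw spot and background brightness. The processed intensity was not normalised between arrays, per the file headers. The same deposited files flag spots that were well above background, saturated or outliers. All 4 arrays lay on 1 slide and came from 1 scan, and the groups occupied different positions of it, so position on the slide and group cannot be told apart. The authors also deposited a log2 value per gene name for each array. Set against the scanner values of the same array, these followed them with a correlation across genes from 0.9987 to 0.9996 on the 4 arrays, in a table of 6224 rows that all matched a gene name in the scanner files. They lie close to the log2 signal after a shift per array (slopes from 0.991 to 0.9955), are not centred by gene, and their medians were -1.41, -1.38, -1.36 and -1.38. The software and settings behind that table are not given in the sources used here.

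The log2 processed signal of each array was reduced by the array's own 75th percentile. Control spots and outlier spots (0.953% of the 15208 gene spots per array) were left out, and 0 spots were saturated. The 2 to 3 spots of a probe were averaged on the log2 scale, and then the probes of a gene. Of the 6256 probes, those of 28 genes shared a gene, and in 0 of these genes did probes differ by more than 1 log2 unit. The array carried 6227 genes under distinct systematic names, of which 5738 matched a reference gene table of assembly R64, and 463 older gene names were updated through it. Other names stand as the files give them. A gene was tested if a probe was well above background on both arrays of at least 1 group, which held for 5688 genes and left out 539. Probe coordinates are those of the files, whose header names the build sacCer1. No genome sequence was used.

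The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3.72 prior and 2 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene passed at an adjusted p below 0.05, and all gene-level adjusted p-values are from this limma fit. A gene that was well above background on both arrays of a group and on neither array of the other has only a bound. It is given as at least a fold: the bright group's mean against the mean, over the dim group's arrays, of the higher of the gene's own signal and the lowest signal well above background. Gene lists were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over 52 lists with at least 5 tested members, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. The percentile of a list's median was taken among 10000 random lists matched on mean signal. The number of arrays limits the precision of every value, and with 2 samples against 2 an exact permutation test cannot go below p = 0.333.

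The groups, the tests, 53 gene lists (3 of whose names had no match on the array), the genes to be named and the alternatives were fixed before the data were examined. The named genes are SPT15, the 12 with the largest passing difference in each direction that were well above background on all 4 arrays, every member of the mevalonate and pyruvate decarboxylation lists, 2 to 4 members of each other list by size of difference among those well above background on all 4 arrays, and up to 5 genes detected in 1 group only. Genes of uncertain annotation or with near-identical copies are named with that remark. The alternatives were other normalisations (array median, quantile), normexp background correction with an offset of 50, the authors' deposited log2 table, other filters on dim probes, outlier spots kept, the brightest probe per gene, an intensity trend with a robust prior, the replicate number as a block, each array left out, and other thresholds. The slide could not serve as a block because there was only 1. With an array left out, its group has 1 sample and the spread comes from the replicates of the other group alone. Whether a gene passes in such a fit therefore depends on which pair remains, and is given as a description only. Scaling on Agilent's spike-in probes was added after seeing the data.

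The fit was tested on simulated data for this comparison, with 200 of 5688 genes changed in each of 20 runs. It recovered 95.9% of the genes changed by 1 log2 unit and 99.6% of those changed by 2, with 8.4 false calls per run on average. It made 0 calls on average where nothing was changed. The phosphate-starvation list, with all its members shifted by 1 log2 unit, was found in 20 of 20 runs. That was with camera at the preset correlation. Camera with an estimated correlation and fry were not run on the simulated data, and smaller list shifts were not simulated. The simulated arrays vary independently, so these figures say nothing of a shared technical difference between the groups. Genes were also drawn independently and with the same spread in both groups, so correlated genes or unequal spreads are not covered. The 200 changed genes exceed the 59 that passed in the data, and the Benjamini-Hochberg adjustment is more lenient where more genes change. The recovery may therefore be lower in the data. There 21 rises and 4 falls of at least 2-fold passed, while ARN1, at 1.69 log2 units, did not (limma adjusted p = 0.0796). Figures were drawn with matplotlib 3.10.9.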

Results

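The series set yeast expressing spt15-A101T, an allele of the gene for the TATA-binding protein, against yeast expressing SPT15-WT. Its title describes the allele as one that increases flux through the mevalonate pathway, the route from acetyl-CoA to sterols and other isoprenoids, and asks for its gene expression signature. Each of the 4 samples, 2 per group, was read on 1 array. The probes well above background numbered 5800 and 5518 of 6256 on the SPT15-WT arrays and 5741 and 5733 on the spt15-A101T arrays. The 75th percentile of the processed signal was 5456 and 5343 for SPT15-WT and 6223 and 7466 for spt15-A101T. Across genes, which are not independent replicates, the replicate arrays correlated at 0.997 for SPT15-WT and 0.995 for spt15-A101T, and the highest correlation between arrays of different groups was 0.992. The replicate difference had an SD over genes of 0.144 log2 units in SPT15-WT and 0.221 in spt15-A101T.

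SPT15 RNA was present at similar levels in both strains. SPT15 (YER148W, probe at 465952 to 466011 on chromosome V) lay 4.33 ± 0.12 log2 units above the array's 75th percentile in SPT15-WT (SD, n = 2) and 4.09 ± 0.03 above it in spt15-A101T (SD, n = 2). The difference of -0.25 ± 0.09 (SE) did not pass the test (limma, adjusted p = 0.240), with a 95% interval from -0.48 to -0.01, and it was 0.15 (adjusted p = 0.766) on the scale of the spike-in probes. Both spt15-A101T arrays were below both SPT15-WT arrays, for which a two-sided exact permutation test gives p = 0.333, the smallest it can give with 2 against 2. The probe does not tell the alleles apart, so it does not check which of them a sample carried.

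Genes of the phosphate-starvation (PHO) regulon held the largest differences, all towards spt15-A101T. PHO5, a secreted acid phosphatase (YBR093C, probe at 430022 to 430081 on chromosome II), rose 34.3-fold (log2 5.10 ± 0.15 SE, n = 2 per group, limma adjusted p = 0.000219). PHO84, the high-affinity phosphate transporter (YML123C, probe at 24138 to 24197 on chromosome XIII), rose 26.0-fold (4.70 ± 0.10, adjusted p = 6.67e-05). SPL2, a regulator of low-affinity phosphate uptake, rose 22-fold (4.46 ± 0.17), PHO89, a sodium-coupled phosphate transporter, 12.5-fold (3.64 ± 0.33), and PHM6 10.3-fold (3.37 ± 0.19). Among subunits of the vacuolar polyphosphate polymerase, VTC3 rose 5.15-fold (2.37 ± 0.10), VTC4 2.97-fold (1.57 ± 0.08) and VTC1 2.18-fold (1.12 ± 0.11). PHO5 and PHO84 passed whichever array was left out. SPL2 (adjusted p = 0.0556), PHM6, VTC3 and VTC4 did not pass without SPT15-WT replicate 2, and PHO89 (adjusted p = 0.153 and 0.267) and VTC1 (0.160 and 0.276) did not without SPT15-WT replicate 1 or 2.

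The acid phosphatases PHO11 and PHO12 rose 4.11-fold and 3.08-fold, and since these genes are near-identical in sequence their probes can share signal. PHO81, the inhibitor of the Pho80-Pho85 kinase, rose 2.35-fold (1.23 ± 0.11). CTF19, a kinetochore gene on the list, was well above background only in spt15-A101T, where it was at least 1.86-fold higher (adjusted p = 0.0471). In all, 12 of the 17 members rose, 0 fell and 5 did not pass: GIT1 (0.77), GDE1 (0.52), PHO8 (0.47), PHO86 (0.44) and PHM8 (0.34). Adjusted over the list alone, 16 were higher. All 17 differences were positive, with a median of 1.62 (1.57 with CTF19 at its bound) and a mean of 2.11. Camera called the list (adjusted p = 1.38e-22). It did not with the correlation estimated from the data (unadjusted p = 0.0827, adjusted p = 0.675 with an estimated correlation), and fry did not (adjusted p = 0.0642). Many lists share the value of 0.675 after adjustment although their unadjusted p-values differ, so it does not measure the single list. Leaving out SPT15-WT replicate 1 or 2 left 8 or 2 members passing, and leaving out spt15-A101T replicate 1 or 2 left 14 or 17. PHM8 alone changed sign, to -0.24 without spt15-A101T replicate 1. PHO11 (adjusted p = 0.0856) and CTF19 (0.240) did not pass without SPT15-WT replicate 2, and PHO12 (0.0583 and 0.0864) and PHO81 (0.130 and 0.267) did not without SPT15-WT replicate 1 or 2. With no filter on dim probes 7 members passed.

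**Figure D1:**
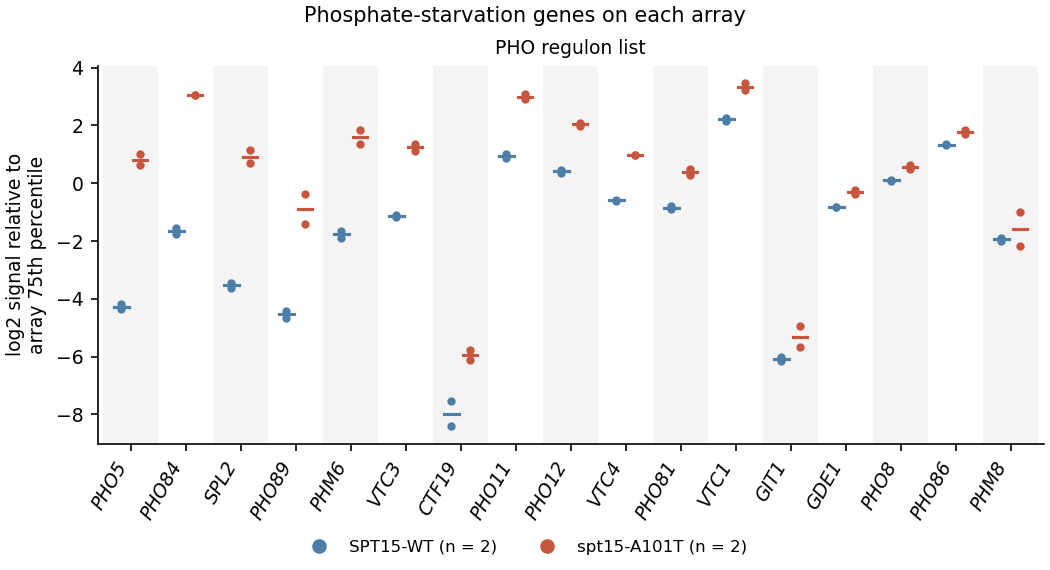
Log2 signal relative to the array's 75th percentile for the 17 members of the PHO regulon list, ordered by difference. Each dot is an array (blue SPT15-WT, red spt15-A101T, n = 2 each) and each line a group mean; PHO5 lies furthest apart, at 5.10 log2 units.

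Over all genes, 47 rose and 12 fell in spt15-A101T (limma, Benjamini-Hochberg), 21 and 4 of them by at least 2-fold. At an unadjusted p below 0.05 there were 1108 genes, against 284 by chance, and in 2997 genes (52.7%, against 33.3% by chance) the arrays of the 2 groups did not overlap. Outside the PHO list, 3 rises were the largest among passing genes well above background on all 4 arrays. They were those of SPS19, a peroxisomal dienoyl-CoA reductase (3.09-fold, log2 1.63 ± 0.11, adjusted p = 0.00397), TIS11, an mRNA-binding protein of the iron response (2.91-fold, 1.54 ± 0.13, adjusted p = 0.0132), and VMR1, a vacuolar ABC transporter (2.83-fold, 1.50 ± 0.18, adjusted p = 0.0300). There were 7 genes well above background in spt15-A101T only and 0 in SPT15-WT only. After CTF19, the highest bounds among these were at least 1.58-fold for SPS2, a sporulation gene (adjusted p = 0.0266), and at least 1.50-fold for the small open reading frame YFR012W-A (adjusted p = 0.0132). OSW1 was at least 1.46-fold higher (adjusted p = 0.0559) and ATR2 at least 1.20-fold (adjusted p = 0.0944). AI4 had a bound of only 1.02-fold, and the open reading frame YOR008C-A did not differ (0.03, adjusted p = 0.964). On SPT15-WT replicate 2 the lowest signal well above background was -6.12 log2 units from the 75th percentile, against -7.96 to -7.00 on the others. Detection in SPT15-WT only was therefore harder to reach. Without SPT15-WT replicate 2 neither SPS19 (adjusted p = 0.110), TIS11 (0.0864), VMR1 (0.276), SPS2 (0.240) nor YFR012W-A (0.0943) passed, and without SPT15-WT replicate 1 TIS11 (0.0672), VMR1 (0.230) and SPS2 (0.0638) did not.

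The falls were smaller. ECM13 was 2.50-fold lower (log2 -1.32 ± 0.08, adjusted p = 0.00347), FUS1, a cell-fusion protein of mating, 2.37-fold lower (-1.25 ± 0.11, adjusted p = 0.0138) and HIS3, an enzyme of histidine synthesis, 2.36-fold lower (-1.24 ± 0.11, adjusted p = 0.0138). MFA1, which encodes the a-factor pheromone, was 2.27-fold lower (-1.18 ± 0.08, adjusted p = 0.00549). YGP1, a secreted glycoprotein, was 1.99-fold lower, PDH1, a mitochondrial enzyme of propionate metabolism, 1.77-fold, CIT1, the mitochondrial citrate synthase, 1.67-fold, DUR12, the urea amidolyase, 1.60-fold, and BAR1, the protease that degrades alpha-factor, 1.55-fold. The other 3 falls were in records of uncertain annotation: the dubious open reading frames YOR203W (-0.93 ± 0.10), which lies next to HIS3, and YMR193C-A (-0.67 ± 0.08), and the unnamed transcript record TC21003 (-0.75 ± 0.10). None of these 12 genes passed in limma without SPT15-WT replicate 1 (ECM13 had the lowest adjusted p, 0.0820) or without SPT15-WT replicate 2 (ECM13, HIS3 and MFA1 each 0.151), and all 12 passed without either spt15-A101T array.

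The counts moved by more than 1.5 times with each array left out. All 59 genes kept their sign, but that was fixed in advance. In none of the 59 did the arrays of the 2 groups overlap, so leaving out an array cannot reverse a difference. Such a fit takes its spread from the group that keeps 2 arrays. The replicate difference had an SD over genes of 0.144 in SPT15-WT and 0.221 in spt15-A101T. Fits without an spt15-A101T array thus rest on the closer pair, so passing there is no added support for a gene. Without SPT15-WT replicate 1 there were 11 rises and 0 falls, and without replicate 2 there were 2 and 1, with 10 and 2 of the 59 calls kept. That 1 fall was ZPS1 (-3.20, adjusted p = 0.0249), chosen after its values were seen. Without spt15-A101T replicate 1 there were 299 rises and 238 falls, and without replicate 2 222 and 48, with all 59 calls kept in each. PHO5 and PHO84 passed in every fit that left out an array. The split of 47 to 12 became 50 to 25 with normexp background correction. Scaled on the spike-in probes, the median gene was 0.42 log2 units (1.33-fold) higher in spt15-A101T and the split was 30 to 0, or 16 to 1 when taken relative to that median. All rises and falls given here are relative to the array's 75th percentile. The spike-in scale adds 0.40 to each difference, so that falls of under 0.40 would be rises there. The spike-in level relative to the 75th percentile was -0.63 and -1.12 in SPT15-WT and -0.96 and -1.58 in spt15-A101T. The replicates of each group thus lay further apart than 0.40. Neither this shift nor the 0.42 of the median gene is therefore shown to be a difference between the groups.

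**Figure D2:**
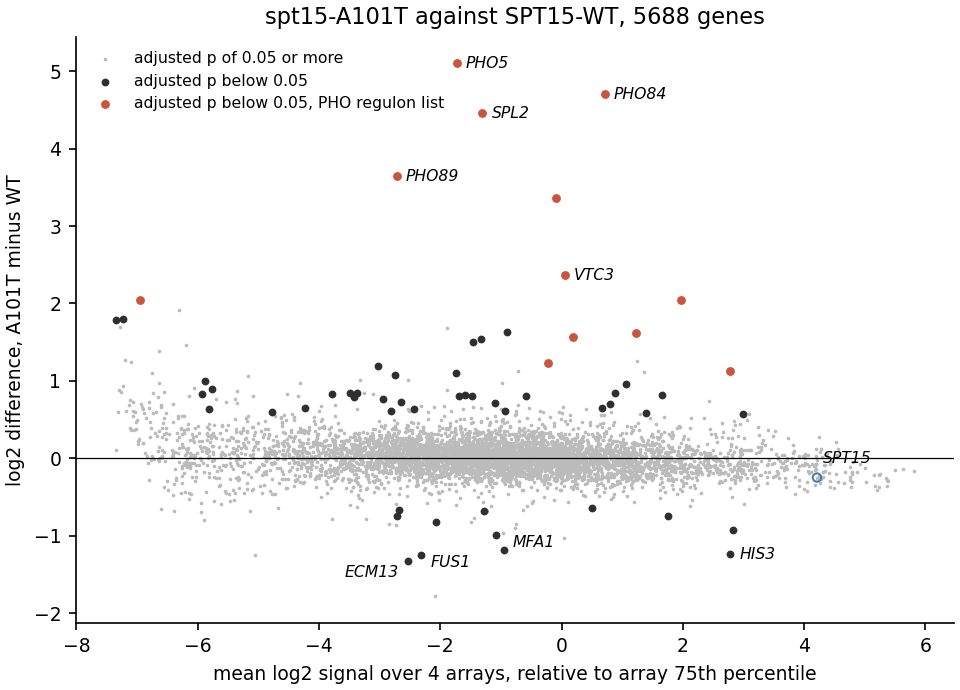
Log2 difference (spt15-A101T minus SPT15-WT) against mean log2 signal over the 4 arrays for 5688 genes. Grey points did not pass, black points passed, and red points passed and belong to the PHO regulon list; SPT15 is circled in blue at -0.25.

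Transcripts of the mevalonate pathway, which the series title names, showed no difference that passed. ERG13, HMG-CoA synthase, had the largest value (0.36 ± 0.10 SE, n = 2 per group, 95% interval 0.12 to 0.61, adjusted p = 0.154), and HMG2, one of the HMG-CoA reductases, the lowest (-0.27 ± 0.08, interval -0.48 to -0.06, adjusted p = 0.185). HMG1, the other reductase, differed by 0.03 ± 0.09 (interval -0.20 to 0.26). The remaining values were 0.15 for ERG12, 0.06 for ERG10, 0.05 for ERG20, -0.01 for IDI1, -0.06 for MVD1, -0.09 for ERG8 and -0.14 for BTS1. None of the 10 members passed over all genes, and 0 did so adjusted over the list alone, while 2 had an unadjusted limma p below 0.05. The median difference was 0.01, camera's direction was down, and its adjusted p was 0.912 (0.960 with an estimated correlation). The median turned to -0.02 with array-median scaling or normexp and to -0.04 without SPT15-WT replicate 1, and ERG13 passed only without spt15-A101T replicate 1 (0.46, adjusted p = 0.0299).

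Genes for pyruvate decarboxylation and acetyl-CoA supply, upstream of that pathway, moved in both directions and none of the 11 passed. PDC6, a minor pyruvate decarboxylase, had the highest value (1.06 ± 0.15, adjusted p = 0.0529). ALD3 (-0.89 ± 0.18, adjusted p = 0.0986) and ALD6 (-0.58 ± 0.09, adjusted p = 0.0609), aldehyde dehydrogenases, had the lowest. PDC1, the main pyruvate decarboxylase, differed by -0.35 ± 0.09 (adjusted p = 0.152). ACS2 was at 0.31, ALD5 at 0.29, ALD4 at 0.13, ALD2 at 0.12, PDC2 at -0.04, ACS1 at -0.09 and PDC5 at -0.15. Adjusted over the list alone, 2 were higher and 3 lower, 5 had an unadjusted p below 0.05, and camera did not call the list (adjusted p = 0.762, median -0.04). With an array left out, PDC6 ranged from 0.85 to 1.28, ALD3 from -1.16 to -0.63, ALD6 from -0.66 to -0.50 and ACS2 from -0.0036 to 0.63.

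**Figure D3:**
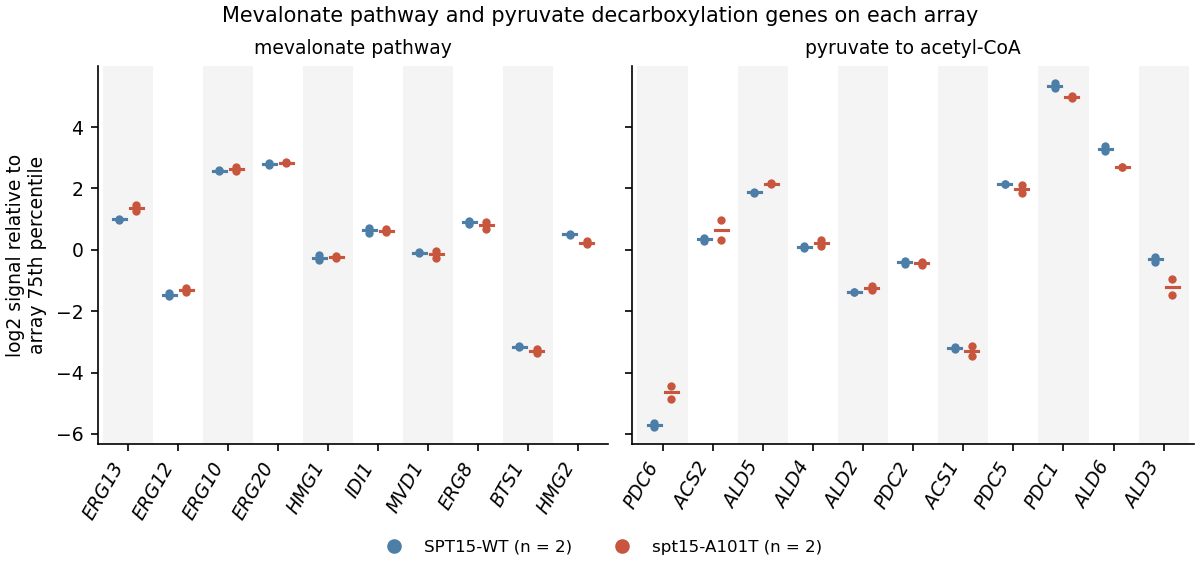
Log2 signal relative to the array's 75th percentile for the 10 mevalonate pathway genes and the 11 pyruvate decarboxylation genes, each ordered by difference. Each dot is an array (blue SPT15-WT, red spt15-A101T, n = 2 each) and each line a group mean; the means of HMG1 lie 0.03 apart and those of PDC6 1.06.

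In the steps after farnesyl diphosphate, which lead to ergosterol, 0 of 15 genes passed in limma, 7 had an unadjusted p below 0.05, and 2 were higher adjusted over the list alone. The largest values were those of ERG5 (0.53 ± 0.08, adjusted p = 0.0587) and ERG3 (0.52 ± 0.08, adjusted p = 0.0659), and the median was 0.16 (camera adjusted p = 0.0638). Among 12 genes of sterol uptake and its regulation, PDR11, a transporter for sterol uptake, rose (0.84 ± 0.08, adjusted p = 0.0169), 4 were higher adjusted over the list alone, and the list was not called (median 0.13, camera adjusted p = 0.135). PDR11 did not pass without SPT15-WT replicate 1 (adjusted p = 0.202) or 2 (0.276), and ERG5 and ERG3 passed without spt15-A101T replicate 1 (0.0148 and 0.0142) or 2 (0.0349 and 0.0409).

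Genes expressed in MATa haploids were lower together. MFA1 and BAR1 fell, and ASG7 (-0.84 ± 0.14, adjusted p = 0.0720), MFA2 (-0.61 ± 0.10, adjusted p = 0.0720) and the other members were lower without passing. Thus 2 of 7 fell over all genes and 6 were lower adjusted over the list alone, with a median of -0.61. Camera called the list (adjusted p = 1.48e-07), but the call was lost with the correlation estimated (unadjusted p = 0.0347, adjusted p = 0.675 with an estimated correlation). Of the 4 tested MATalpha markers 0 passed, and STE3, the a-factor receptor, was at 0.87 ± 0.20 (adjusted p = 0.125) and alone was higher adjusted over the list alone. MATALPHA1 (0.02) and MATALPHA2 (-0.04), whose probes can share signal with the silent mating cassettes, were near 0, and the alpha-factor genes were not well above background on any array. In the list of haploid and pheromone-response genes, FUS1 was the 1 of 17 that fell, 2 were lower adjusted over the list alone, and the list was not called (median -0.17, camera adjusted p = 0.0638). AGA1 was at -0.47 (adjusted p = 0.166) and KAR4 at -0.41 (adjusted p = 0.0982), while 6 of the 17 were above 0. The highest of these was PRM2 (0.68, adjusted p = 0.159), which was dim in SPT15-WT and was chosen after its values were seen. MFA1 (adjusted p = 0.106 and 0.151), BAR1 (0.293 and 0.413) and FUS1 (0.160 and 0.267) did not pass without SPT15-WT replicate 1 or 2. ASG7 (0.00448 and 0.0239), MFA2 (0.0236 and 0.00864) and STE3 (0.0426 and 0.00656) passed without spt15-A101T replicate 1 or 2.

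Iron uptake genes were mostly higher in spt15-A101T, with wide spread. TIS11 rose, while ARN1 (1.69 ± 0.30, adjusted p = 0.0796) and SIT1 (1.13 ± 0.32, adjusted p = 0.162), siderophore transporters, and FET3, the ferroxidase of high-affinity uptake (1.26 ± 0.28, adjusted p = 0.123), did not pass. So 1 of 25 members rose, 11 were higher adjusted over the list alone, and 20 had a positive difference, with a median of 0.43. Camera called the list (adjusted p = 3.43e-06), but not with an estimate of the correlation (adjusted p = 0.675 with an estimated correlation). TIS11 did not pass without SPT15-WT replicate 1 (adjusted p = 0.0672) or 2 (0.0864). ARN1 passed without spt15-A101T replicate 1 (0.00286) or 2 (0.0204), and FET3 (0.0379) and SIT1 (0.0359) without spt15-A101T replicate 1.

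**Figure D4:**
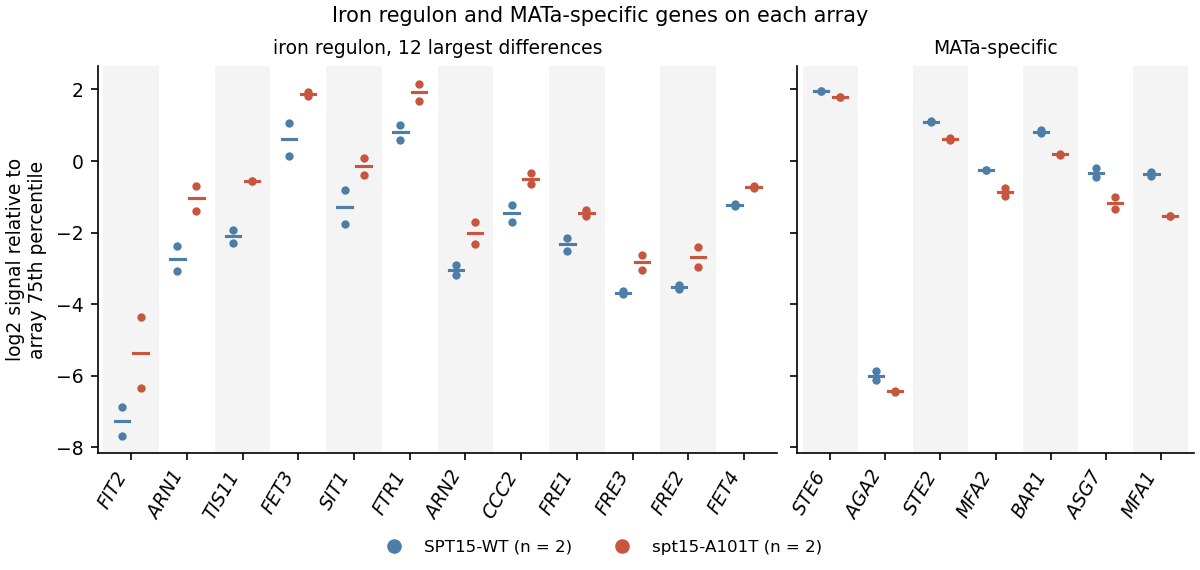
Log2 signal relative to the array's 75th percentile for the 12 iron regulon genes with the largest differences and the 7 MATa-specific genes. Each dot is an array (blue SPT15-WT, red spt15-A101T, n = 2 each) and each line a group mean; the difference is 1.54 for TIS11 and -1.18 for MFA1.

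Another 3 lists were called towards higher in spt15-A101T. In beta-oxidation and peroxisome genes, SPS19 and POX1 (0.84 ± 0.09, adjusted p = 0.0252), the acyl-CoA oxidase, rose among 14. POX1 was chosen after its values were seen. PEX11 was at 0.60 (adjusted p = 0.0982), 6 were higher adjusted over the list alone, and the median was 0.24 (camera adjusted p = 0.000712, adjusted p = 0.675 with an estimated correlation). In G1/S and S-phase genes 0 of 17 passed in limma, 8 had an unadjusted p below 0.05, all 17 were positive and 6 were higher adjusted over the list alone. POL30, the replication clamp, was at 0.55 ± 0.08 (adjusted p = 0.0529), MCD1, a cohesin subunit, at 0.56 and CLB6, an S-phase cyclin, at 0.56, and the median was 0.18 (camera adjusted p = 0.000146, adjusted p = 0.675 with an estimated correlation). In meiosis and sporulation genes, SPS4 (1.19 ± 0.13, adjusted p = 0.0252) and SPS2 rose among 13, 4 were higher adjusted over the list alone, and the median was 0.37 (camera adjusted p = 0.00313, adjusted p = 0.675 with an estimated correlation). IME2, a kinase of meiotic entry, was at 0.44 (adjusted p = 0.0822). The camera call for meiosis ended with normexp (median 0.03, adjusted p = 0.313) and without spt15-A101T replicate 1 (median 0.26, adjusted p = 0.0588). It held with normexp and quantile normalisation (median 0.06, adjusted p = 0.0469). SPS19 did not pass without SPT15-WT replicate 2 (adjusted p = 0.110), nor POX1, SPS4 and SPS2 without SPT15-WT replicate 1 (0.160, 0.0964 and 0.0638) or 2 (0.335, 0.267 and 0.240). POL30, MCD1 and CLB6 passed without spt15-A101T replicate 1 (0.0166, 0.00939 and 0.0198) or 2 (0.0263, 0.0388 and 0.0425), and PEX11 (0.0234) and IME2 (0.0296) without replicate 1.

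The lists called towards lower, besides the MATa genes, were 5, each by a small median. Of 136 ribosomal protein genes 0 passed in limma (27 at an unadjusted p below 0.05), 0 did so adjusted over the list alone, and 113 were below 0, with a median of -0.11 (camera adjusted p = 7.48e-08, adjusted p = 0.675 with an estimated correlation). RPL18B (-0.56 ± 0.14, adjusted p = 0.135) and RPS9A (-0.56 ± 0.10, adjusted p = 0.0732) had the lowest values and RPL39 (0.48 ± 0.11, adjusted p = 0.123) the highest. RPL18B passed without spt15-A101T replicate 1 (0.0121), RPS9A without replicate 1 or 2 (0.0129 and 0.0439) and RPL39 without replicate 2 (0.0180). The ribosomal call ended under quantile normalisation (median -0.06, adjusted p = 0.143), also after normexp (median -0.06, adjusted p = 0.170). All 14 genes of the pyruvate dehydrogenase complex and bypass transport were below 0 and none passed in either adjustment, over all genes or adjusted over the list alone (MPC2, a mitochondrial pyruvate carrier subunit, -0.46 ± 0.12, and LPD1 -0.38 ± 0.11), with 4 at an unadjusted p below 0.05. MPC2 passed without spt15-A101T replicate 1 (0.0138) and LPD1 without replicate 2 (0.0290). Their median was -0.18 (camera adjusted p = 0.00242, adjusted p = 0.675 with an estimated correlation).

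HIS3 was the 1 of 7 histidine synthesis genes that fell, and 3 were lower adjusted over the list alone. HIS5 was at -0.38 ± 0.09 (adjusted p = 0.130), and the median was -0.19 (camera adjusted p = 0.0170, adjusted p = 0.675 with an estimated correlation). The histidine call ended without SPT15-WT replicate 2 (adjusted p = 0.0591) or spt15-A101T replicate 1 (adjusted p = 0.0643), and with quantile normalisation alone (adjusted p = 0.0505) or after normexp (adjusted p = 0.0612). In the tricarboxylic acid cycle CIT1 was the 1 of 17 that fell, 2 were lower adjusted over the list alone, ACO1, aconitase, was at -0.50 ± 0.10 (adjusted p = 0.0984), and the median was -0.06 (camera adjusted p = 0.0201, adjusted p = 0.675 with an estimated correlation). That median lay at percentile 25.04 of random lists matched on mean signal, so such lists often had a median as low. Of 34 respiratory chain and ATP synthase genes 0 passed in either adjustment, over all genes or adjusted over the list alone (QCR9 -0.40 ± 0.18, CYC1 0.35 ± 0.09), with 12 at an unadjusted p below 0.05 and a median of -0.07 (camera adjusted p = 0.0170, adjusted p = 0.682 with an estimated correlation). The tricarboxylic acid call ended without spt15-A101T replicate 1 (adjusted p = 0.134), and the respiratory call without SPT15-WT replicate 1 (adjusted p = 0.0648) or spt15-A101T replicate 2 (adjusted p = 0.161). Both also ended with normexp (adjusted p = 0.110 and 0.0585) and with spike-in scaling relative to the median gene (adjusted p = 0.0584 and 0.0633), and the tricarboxylic acid call with normexp and quantile normalisation (adjusted p = 0.0920). HIS3 (0.130 and 0.151) and CIT1 (0.311 and 0.344) did not pass without SPT15-WT replicate 1 or 2, while HIS5 (0.0463) and QCR9 (0.0223) passed without spt15-A101T replicate 1 and ACO1 (0.0202) without replicate 2.

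Camera thus called 11 of 52 lists, 5 higher and 6 lower, against 0 with an estimated correlation and 0 by fry. At an unadjusted p below 0.05 these numbers were 18, 2 and 13. The estimated correlation rests on 2 residual degrees of freedom, and neither camera with it nor fry was run on the simulated data. Even the PHO list, with all 17 differences positive, had an unadjusted camera p of 0.0827 with an estimated correlation. The lack of calls there does not show that the lists did not shift, and it leaves the calls at the preset correlation unsettled. Against random lists matched on mean signal, the medians of the higher called lists lay at percentile 99.84 or above. Those of the lower called lists lay at 3.68 or below, apart from the tricarboxylic acid cycle at 25.04. Some lists that were not called also lay near the ends. Stationary phase was at 0, haploid and pheromone response at 0.05 and sterol synthesis after farnesyl diphosphate at 99.97. The random lists ignore correlation between genes. Among lists that camera did not call, ECM13 fell in the stationary-phase list (14 tested, median -0.29, camera adjusted p = 0.0649), where 4 were lower and 1 higher adjusted over the list alone. DUR12 fell among 24 genes of nitrogen catabolite repression (median -0.07, adjusted p = 0.0638), where 6 were lower and 1 higher adjusted over the list alone. There GAP1, the general amino acid permease, was at -1.03 ± 0.17 (adjusted p = 0.0671) and MEP2, an ammonium permease, at -0.96 ± 0.17 (adjusted p = 0.0736). GAD1, glutamate decarboxylase, rose 2.15-fold (adjusted p = 0.00926) and YGP1 fell among 25 general stress genes (median -0.04, adjusted p = 0.152), where 1 was higher and 2 were lower adjusted over the list alone. MTH1, a repressor of hexose transporter genes, rose (1.08 ± 0.09, adjusted p = 0.0127) as 1 of 8 on the galactose list (median 0.14, adjusted p = 0.170), and 1 was higher adjusted over the list alone. OYE3, an NADPH oxidoreductase, rose (0.85 ± 0.10, adjusted p = 0.0346) as 1 of 19 on the oxidative stress list (median 0.10, adjusted p = 0.170), and 3 were higher adjusted over the list alone. KDX1 rose (0.73 ± 0.08, adjusted p = 0.0286) as 1 of 18 cell wall genes (median 0.09, adjusted p = 0.545), and 2 were higher adjusted over the list alone. HIS3 was the only one of 6 tested auxotrophic markers to fall, over all genes and adjusted over the list alone (median -0.11, adjusted p = 0.309). Without SPT15-WT replicate 1 or 2 none of ECM13, DUR12, GAD1, YGP1, MTH1, OYE3, KDX1 and HIS3 passed (lowest adjusted p 0.0820, for ECM13). GAP1 (0.00140 and 0.0111) and MEP2 (0.000849 and 0.00936) passed without spt15-A101T replicate 1 or 2.

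The other lists held no gene that passed over all genes in limma, and 94 of their genes had an unadjusted p below 0.05. Among those for the transcription machinery, 0 genes passed adjusted over the list alone either, and the medians were 0.10 for the TATA-binding protein and its regulators (camera adjusted p = 0.595), -0.02 for TFIID (adjusted p = 0.817), 0.0061 for SAGA (adjusted p = 0.975) and 0.0016 for RNA polymerase II (adjusted p = 0.601). The largest values there were SUA7 (0.35 ± 0.08) and TAF10 (0.35 ± 0.08). In carbon metabolism they were -0.15 for glycolysis (adjusted p = 0.135), 0.02 for gluconeogenesis and the glyoxylate cycle (adjusted p = 0.881), -0.01 for the pentose phosphate pathway (adjusted p = 0.762), 0.10 for hexose transporters (adjusted p = 0.595), 0.05 for alcohol dehydrogenases (adjusted p = 0.937) and -0.02 for trehalose and glycogen (adjusted p = 0.912). In the synthesis of amino acids and nucleotides they were -0.04 for arginine (adjusted p = 0.817), -0.02 for lysine (adjusted p = 0.817), 0.07 for leucine, isoleucine and valine (adjusted p = 0.912), -0.11 for sulfur and methionine (adjusted p = 0.190), -0.01 for aromatic amino acids (adjusted p = 0.428) and -0.06 for purines (adjusted p = 0.791).

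Medians for thiamine, phospholipid synthesis and fatty acid synthesis were 0.05 (adjusted p = 0.699), -0.03 (adjusted p = 0.706) and 0.07 (adjusted p = 0.817). For ribosome biogenesis, chaperones, histones and the PAU family, whose probes can share signal between copies, they were 0.09 (adjusted p = 0.105), -0.12 (adjusted p = 0.116), -0.09 (adjusted p = 0.170) and -0.04 (adjusted p = 0.170). Zinc and copper genes had a median of 0.10 (adjusted p = 0.135), hypoxic genes -0.08 (adjusted p = 0.382), multidrug resistance genes 0.0018 (adjusted p = 0.912) and flocculation genes 0.12 (adjusted p = 0.545). M/G1 genes had a median of 0.10 (adjusted p = 0.0734) and mitotic genes 0.07 (adjusted p = 0.601). In these lists up to 5 genes passed when adjusted over the list alone: 1 higher and 4 lower for thiamine, 3 higher for zinc and copper, 1 higher and 2 lower for purines and for lysine, and 1 in either direction for glycolysis, aromatic amino acids and flocculation. M/G1 had 1 higher, and mitosis and fatty acid synthesis 1 lower. The median, mean and camera direction did not all have the same sign for gluconeogenesis, alcohol dehydrogenases, trehalose and glycogen, lysine, thiamine, multidrug resistance, TFIID, SAGA, RNA polymerase II and the mevalonate pathway.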

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

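The spike-in scaling was chosen only after the results were seen. All 59 genes that passed kept their sign in every alternative that tested them, and 52 were well above background on all 4 arrays. With an array left out the sign was fixed in advance, since in none of the 59 did the arrays of the 2 groups overlap. The 47 rises and 12 falls became 21 and 4 with a 2-fold minimum, 139 and 50 at an adjusted p below 0.1, 82 and 33 with normexp and quantile normalisation, 7 and 1 with no filter on dim probes, 74 and 28 with genes well above background on all 4 arrays only, 103 and 48 with an intensity trend and robust prior, and 30 and 0 with spike-in scaling, or 16 and 1 relative to its median gene. The falls alone moved to 21 with quantile normalisation, 25 with normexp and 6 at an unadjusted p with a 2-fold minimum. Fewer or more genes tested and the stricter thresholds account for part of this by construction, and the cause was not tested for the others. The samples with the same replicate number share only a number (their deviations correlated at 0.132 across genes, with 2 pairs), and with the replicate block 185 genes rose and 75 fell, with all 59 calls kept.

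Leaving out each array in turn gave 2 to 299 rises and 0 to 238 falls: 11 and 0 without SPT15-WT replicate 1, 2 and 1 without SPT15-WT replicate 2, 299 and 238 without spt15-A101T replicate 1, and 222 and 48 without spt15-A101T replicate 2. A single array is there assumed to vary like the other group. The 11 lists called by camera were 0 with an estimated correlation and 0 by fry, and 10 to 13 with an array left out. The mevalonate median of 0.01 turned to -0.022 with array-median scaling, -0.016 with normexp, -0.0095 with normexp and quantile normalisation and -0.0057 with spike-in scaling relative to the median gene, and ranged from -0.040 to 0.039 with an array left out, negative without SPT15-WT replicate 1. With an array left out, values short of passing changed sign for ERG8 (-0.21 to 0.024), HMG1 (-0.047 to 0.11), IDI1 (-0.085 to 0.062), MVD1 (-0.16 to 0.035), ACS1 (-0.27 to 0.082), ACS2 (-0.0036 to 0.63), PDC2 (-0.082 to 0.0046), PHM8 (-0.24 to 0.93), PHO80 (-0.10 to 0.035), PHO91 (-0.13 to 0.026), MRM1 (-0.23 to 0.059), MATALPHA1 (-0.18 to 0.21), MATALPHA2 (-0.11 to 0.041) and ZRT1 (-1.47 to 0.25). MATALPHA1 was also at -0.014 with array-median scaling, -0.024 with quantile normalisation, -0.10 with normexp and -0.071 with normexp and quantile normalisation. None of these genes had passed, and the cause was not tested.

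For the named genes, 1345 of 1528 values under the other alternatives kept their direction and side of the threshold, 83 no longer passed, 96 newly passed and 4 reversed. With an array left out these were 355, 70, 68 and 19 of 512. For the 11 lists, 122 of 154 calls were kept and 32 lost. All 11 were lost with an estimated correlation and all 11 with fry, so these tests account for most of the 32. The SPT15 difference did not pass under any alternative (adjusted p from 0.167 to 0.778 with an array left out). It was negative under all but plain spike-in scaling, where it was 0.15 (adjusted p = 0.766). That scaling adds 0.40 to every difference, a shift smaller than the spread of the spike-in level between replicates. The slide could not be a block, with 1 slide. For dim genes, signal over background limits the values: the lowest signal well above background lay between -7.96 and -6.12 log2 units from the 75th percentile on the 4 arrays.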

Other observations

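The tests on HIS3 and the test on array background were chosen only after the results they bear on were seen, and so were the genes named here that lie outside the fixed lists. Around the PHO regulon, PHO81, an inhibitor of the Pho80-Pho85 kinase, rose, while 4 other regulators did not pass. PHO4, the activator of the pathway, differed by 0.18, PHO2 by -0.06, PHO80 by -0.03 and PHO85 by -0.13 (limma adjusted p from 0.382 to 0.860). The low-affinity transporters PHO87, PHO90 and PHO91 were at -0.40, -0.24 and -0.05, also without passing. PHO3, the acid phosphatase gene beside PHO5, was at -0.49 (adjusted p = 0.0944) where PHO5 rose by 5.10. VTC2, a polyphosphate polymerase subunit outside the fixed list, rose by 0.59 ± 0.08 (adjusted p = 0.0438). Further rises included COX17, a copper chaperone for cytochrome oxidase (0.96 ± 0.09, adjusted p = 0.0164), GPP2, a glycerol phosphatase (0.85 ± 0.11, adjusted p = 0.0438), YHB1, a flavohemoglobin that removes nitric oxide (0.82 ± 0.09, adjusted p = 0.0223), and TAT1, an amino acid permease (0.71 ± 0.09, adjusted p = 0.0438). None of VTC2, COX17, GPP2, YHB1 and TAT1 passed without SPT15-WT replicate 1 (adjusted p from 0.134 to 0.362) or 2 (0.276 to 0.413). PHO3 passed without spt15-A101T replicate 1 or 2 (0.0448 and 0.0235), and PHO87 without replicate 1 (0.0370).

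Around HIS3, the dubious open reading frame YOR203W, whose probe lies between the HIS3 probe and DED1, was also lower (-0.93), while DED1 was at 0.55 (adjusted p = 0.0703, but 0.0198 and 0.0404 without spt15-A101T replicate 1 or 2) and MRM1, on the other side, at -0.09. Of the other common marker genes, LEU2 and MET17 were not well above background on any array and URA3 was at -0.32 (adjusted p = 0.194). Of the zinc regulon, ZRT1 (-0.61 ± 0.67) differed more between the replicates of each group than between groups. ZPS1 (-1.78 ± 0.85) did so in SPT15-WT only, where its replicates were at 0.22 and -2.62, against -3.04 and -2.91 in spt15-A101T. It ranged from -3.20 without SPT15-WT replicate 2, where it passed (adjusted p = 0.0249), to -0.36 without SPT15-WT replicate 1, and it passed with spike-in scaling relative to the median gene (adjusted p = 0.00618). Among the 59 changed genes 2 pairs were chromosomal neighbours, VTC3 with CTF19 and PHO81 with YHB1, and a share of 0.0799 of 10000 random draws held as many, so clustering of changed genes along chromosomes was not shown.

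The 7 MATa-specific genes all had negative differences, with a mean of -0.63, of which 2 passed. Camera called the list (adjusted p = 1.48e-07), but not with an estimated correlation (adjusted p = 0.675 with an estimated correlation), and fry did not (0.0642). Admixed MATalpha cells would bring abundant alpha-factor transcripts. MF(ALPHA)1 and MF(ALPHA)2 were not well above background on any array, which argues against such cells as the source of the whole difference. Their mean difference of -0.0703 (SE 0.275) lies within background and adds nothing to this. The MATalpha genes STE3 (0.87, adjusted p = 0.125) and SAG1 (0.23, adjusted p = 0.398) lay in the direction that admixture predicts, without passing. Admixed diploids would lower the constitutive haploid genes STE4, STE5, STE18 and GPA1 as much. These lay 0.596 above the MATa genes, which argues against diploids as the source of the whole difference. The SE of this gap (0.136) is over genes read on the same arrays, not over samples. Lower pheromone-pathway output may remain a part of the difference. The 8 pheromone-induced genes other than FUS1 had a mean of -0.148 (SE over genes 0.139), 6 of them below 0, too wide a spread to tell. An effect of the spt15-A101T allele on MATa-gene promoters stays open and untested.

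HIS3 fell by 1.24 on the log2 scale. The other 6 histidine synthesis genes lay 1.09 above HIS3 on average (SE 0.136, partly over genes), so they did not fall as much. HIS3 was chosen because it fell the most among them. The gap therefore cannot exclude a smaller fall shared by the list as a part of the HIS3 value. Fewer copies of a construct that carries both genes would lower SPT15 too, and SPT15 lay 0.99 (SE 0.146) above HIS3. SPT15 was among the brightest genes, at rank 48 and 55 of 6227 on the SPT15-WT arrays and 62 and 70 on the spt15-A101T arrays. How much of that signal came from a genomic SPT15 copy is not known, since no sample without the expressed allele was measured. The labels also do not say where either gene is carried, so fewer copies of a shared construct stay open. A response of the HIS3 promoter, which has a TATA element, to the altered TATA-binding protein is a hypothesis that was not tested.

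Sporulation genes had a median difference of 0.37 over 13 genes, mostly of low signal. Of these, 10 were well above background on all 4 arrays, 2 passed and 2 were below 0. Camera called the list (adjusted p = 0.00313), but not with an estimated correlation (adjusted p = 0.675 with an estimated correlation), with normexp at the 75th percentile (0.313; 0.0469 with quantile normalisation) or without spt15-A101T replicate 1 (0.0588), and fry did not call it (0.154). In the processed signal, a share of 0.0029 of 10000 random lists matched on mean signal had a median as high. Genes of similar signal thus did not rise as much in general there. The random lists ignore correlation between genes and were not drawn with normexp, so they do not exclude an effect of low signal. Higher background on the spt15-A101T arrays stays open: their negative controls lay -0.347 (SE 0.702) from those of SPT15-WT on average, too wide a spread to tell. The way background is subtracted also stays open as a candidate explanation, since the median was 0.03 with normexp and 0.06 with normexp and quantile normalisation. An effect of the spt15-A101T allele stays open, as a hypothesis that was not tested.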
